A study of Homo sapiens with 9 samples.

How the data were processed

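Cells of human cardioids of 5 subtypes were profiled with the 10x Genomics Flex assay in 9 libraries, 2 each of LV, RV, OFT and AVC and 1 of Atria, whose titles carry 3 different leading numbers of unstated meaning. Groups, replicates, tags, doses and days were taken from the labels. Counting with Cell Ranger 7.1.0 on GRCh38 and processing with R 4.2.2 and Seurat 4.3.0 are named in the submitters' processing notes. The deposited matrix held raw UMI counts per gene and cell, whole numbers that summed in each cell to the count in the deposited cell table, without normalization, per the file headers. The deposited cell table also gave the percent of a cell's UMI counts on mitochondrial genes and the authors' cell type of each cell. The filters applied to cells and genes before deposit, their thresholds and how the cell types were assigned are not given in the sources used here. The lowest deposited UMI count of a cell was 2196.

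No cell was removed here and no clustering was made. No doublet caller was run, the deposited annotation was used as it is, and leaving out the top 2% of cells by UMI count in each library was tried as an alternative. The cardiomyocyte class comprised 9 of the 11 deposited types, all except EC and Endoderm, and included the proliferating types. Its counts were summed per library, and 1 CPM corresponds to 39.5 counts in the shallowest and 182 in the deepest library, so counting error is small above a few CPM. Each library, not each cell, was a replicate. Shares of cells are percent of all deposited cells of a library, with exact Clopper-Pearson 95% intervals and, for 0 cells, the limit that 3 cells set, and these cover counting error only.

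Differential expression was computed in R 4.3.3 with edgeR 4.0.16 on the 8 libraries of the replicated subtypes, which shared 1 estimate of the spread with 4 residual degrees of freedom. Genes were kept by filterByExpr (15063 genes), scaled by TMM, fitted with glmQLFit and tested two-sided with glmQLFTest, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The common biological coefficient of variation was 0.260. Contrasts were each subtype minus the mean of the log2 values of the 3 others, LV minus RV, OFT minus RV, and any difference among the 4. Because the fit shares its spread, a library left out of one subtype changes the tests of all contrasts. Where a subtype was left with 1 library, that library was assumed to vary like those of the other groups. Atria was described by log2 CPM with a prior count of 2 and a rule on size and range without a test. Of 23 gene lists written before the data were examined, each was tested in 6 contrasts with camera of limma 3.58.1, a test against all other genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over all 138 tests. With an estimated correlation 0 of the 58 calls held. For Atria, list medians were placed among those of 10000 random lists of equal size, matched on mean expression. Random members were drawn independently, so correlation between the genes of a list was ignored.

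The genes named for a contrast were the 10 higher and 10 lower genes of largest absolute log2 fold change that passed, had a mean of at least 20 CPM on the higher side and did not overlap between the libraries of the sides, and from each list up to 4 members. Genes fixed by name were reported in every library. Some single genes that met these rules are not reported here. The subtypes and contrasts, the gene lists, the rule for naming genes and a first set of alternatives were chosen before the data were examined. These alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, all deposited cells, 7057 cells drawn per library, the tag as a block, each library left out, a fold threshold and Atria among the others, and for Atria the prior count, the scaling, the size rule and the TNI libraries alone. Leaving out proliferating cells, leaving out the top 2% of cells by UMI count before summing and thinning every library sum to the smallest were added after the data were seen. Fits of EC cells summed per library, with at least 20 cells of the class, were also chosen after the data were seen.

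The code was tested on simulated counts for 15063 genes with the real library sizes and each gene's real mean over all libraries. Every subtype had the same spread and no shift between tags was simulated, and 67 genes were changed 2-fold. Of these 52.2% were recovered for LV, 37.3% for RV, 35.8% for OFT, 47.8% for AVC, 34.3% for LV against RV and 29.9% for OFT against RV. At 8-fold the shares were 90.9%, 92.4%, 87.9%, 92.4%, 86.4% and 89.4% in the same order, with 3 to 22 false calls among 14843 unchanged genes. In the data the SD over genes of the log2 difference TNI minus TNT2 was 0.827 in RV and 0.459 in LV. The shares therefore check the code and do not give the power of each real contrast. Positions came from GENCODE version 29 on GRCh38, which held 16186 of the deposited symbols. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.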

Results

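Gene expression was measured in single cells of human cardioids, which are self-organising heart organoids grown from pluripotent stem cells, here of the WTC line, an established human induced pluripotent stem cell line. The assay was 10x Genomics Flex, which counts RNA molecules with gene-specific probes in fixed cells. Protocols for 5 cardiac subtypes were compared: left ventricle (LV), right ventricle (RV), outflow tract (OFT), atrioventricular canal (AVC) and atria. LV, RV, OFT and AVC had 2 libraries each and Atria had 1, so that no value of Atria has a replicate error. The series design text calls the libraries biological replicates, and the 2 libraries of each replicated subtype carry different tags in their titles, TNI and TNT2, whose meaning the labels do not give. Atria carries TNI. LV cardioids were collected on day 7.5 and the others on day 9.5, so the subtype and the day cannot be told apart for LV. The libraries held 7613 to 12187 cells each. Their UMI counts (counted RNA molecules) summed to 42095480 in AVC replicate 2, the shallowest, and 201060352 in LV replicate 1, the deepest, with medians of 4713 to 14002 UMI counts per cell. Expression is given in CPM, UMI counts scaled to a common library total, of the summed cardiomyocyte-class cells of a library, with the mean, the SD and n = 2 libraries. Fold changes are log2 with their standard error (SE, the absolute log2 fold change divided by the square root of the edgeR F statistic). Gene positions are those of GRCh38.

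Most deposited cells carried a cardiomyocyte type in the authors' annotation, and the remaining cells were called EC (endothelial) or Endoderm. The question was how far each protocol gave cardiomyocytes. The cardiomyocyte class made up 99.5% ± 0.715 of OFT cells (mean ± SD, n = 2), 99.2% ± 0.660 of RV cells, 96.5% ± 0.285 of AVC cells and 94.3% ± 3.51 of LV cells. In Atria it was 88.1%, with an exact Clopper-Pearson 95% interval of 87.4% to 88.8%. EC cells were most frequent in Atria, at 8.24% (7.64% to 8.86%), and made up 2.41% ± 0.929 of LV, 2.25% ± 0.564 of AVC, 0.621% ± 0.508 of RV and 0.285% ± 0.368 of OFT cells. Endoderm cells were 6.40% of LV replicate 1 but 0.127% of LV replicate 2, and 3.68% of Atria. OFT replicate 2 had 0 of 12187 cells in that class, which allows a share of up to 0.0246%. Cells of the authors' proliferating cardiomyocyte types made up 21.2% of OFT replicate 2 and 3.49% of OFT replicate 1, and 3.97% of RV replicate 2 against 0.0735% of RV replicate 1. With 2 libraries against 2 an exact permutation test cannot give a p below 0.333, and no share was tested between subtypes.

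Markers fixed beforehand for cardiomyocytes, endothelium and endoderm were highest in the class of that name, and EC cells also carried mesenchymal markers. Cardiomyocyte markers averaged 2829.9 CPM in the cardiomyocyte class, 406 in EC and 202 in Endoderm cells. Endothelial or endocardial markers averaged 604 CPM in EC cells, led by KDR, a receptor of vascular endothelial growth factor, at 2537 CPM, and 32.7 CPM in the cardiomyocyte class. Fibroblast or mesenchymal markers averaged 289 CPM in EC cells and 86.3 CPM in the cardiomyocyte class. Endoderm markers averaged 1174 CPM in Endoderm cells, led by AFP (alpha-fetoprotein) at 3059 CPM, and 17.7 CPM in the cardiomyocyte class.

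**Figure D1:**
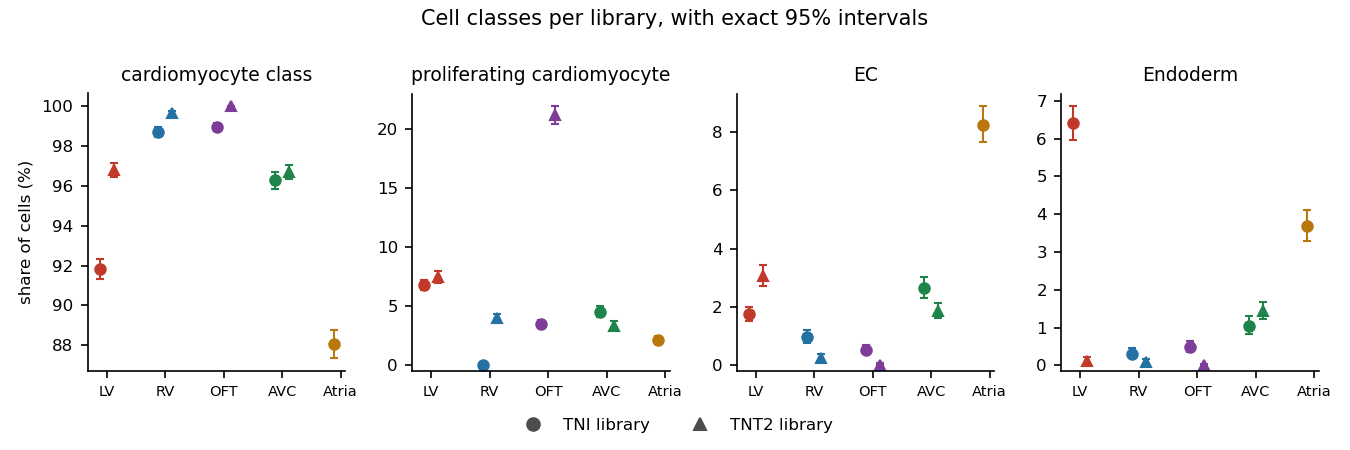
Share of cells (percent) of the cardiomyocyte class, its proliferating types, EC and Endoderm in each of the 9 libraries, with exact 95% intervals; circles are TNI and triangles TNT2 libraries. The proliferating share of OFT was 21.2% in replicate 2 and 3.49% in replicate 1.

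The libraries of one subtype lay closest to each other in 7 of the 8 libraries of the replicated subtypes. Across the 15063 genes tested, Pearson's r of log2 CPM between the libraries of a subtype was 0.991 for LV, 0.987 for AVC, 0.983 for OFT and 0.970 for RV, and genes are not independent replicates. The exception was RV replicate 2, whose best partner was LV replicate 2 (r = 0.982), also a TNT2 library. The mean r was 0.983 within subtypes, 0.961 between subtypes of the same tag and 0.957 between subtypes of different tags.

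**Figure D2:**
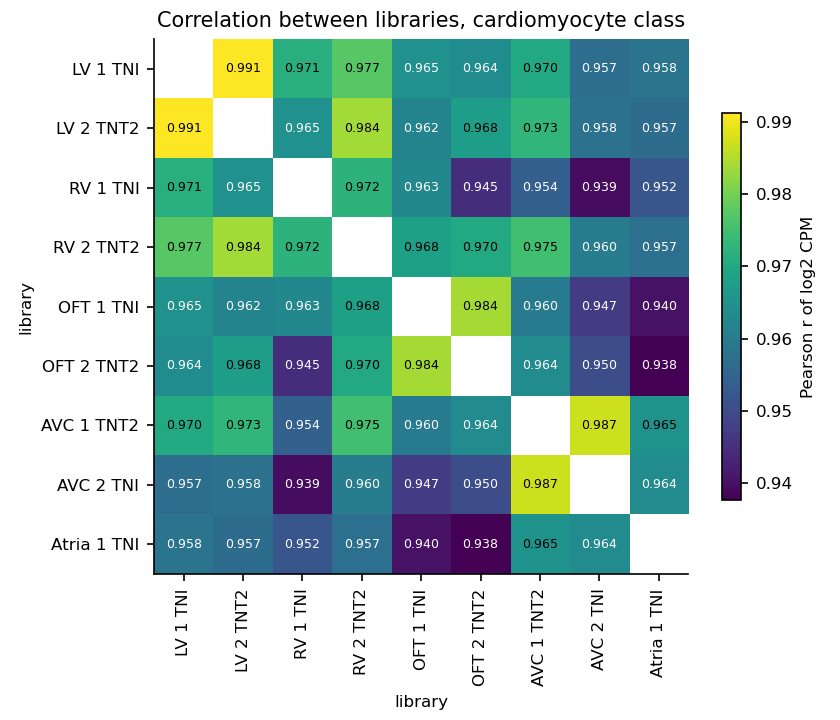
Pearson correlation of log2 CPM between the 9 libraries, over the 15383 genes kept when Atria was included, which moves single values slightly from those of the 8-library fit. Each library is named by subtype, replicate and tag.

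The cardiac genes TNNT2 and NKX2-5 were expressed in every library, while NR2F1, NR2F2, WNT5A, TBX5, TBX2, TBX3 and IRX4 varied among the replicated subtypes. The cardiac troponin gene TNNT2 (chromosome 1, 201359008 to 201377762) lay between 5104 and 10983 CPM over the 9 libraries, and NKX2-5, a cardiac transcription factor, between 482 and 854 CPM. The orphan nuclear receptor gene NR2F2 (chromosome 15, 96325938 to 96340263) was 187 ± 11.8 CPM in AVC and 579 CPM in Atria, against 2.13 ± 0.00967 in LV, 4.89 ± 1.64 in RV and 2.39 ± 1.55 in OFT. TBX5, a T-box gene of the first and posterior second heart fields, was 772 ± 124 CPM in AVC and 134 ± 66.3 CPM in OFT, and TBX2, a T-box repressor of the chamber programme, was 513 ± 63.5 CPM in AVC and 75.5 ± 12.0 CPM in LV. WNT5A (chromosome 3, 55465715 to 55490539) was 326 ± 125 CPM in OFT and 85.0 ± 14.9 CPM in LV. The ventricular gene IRX4 was 158 ± 15.2 CPM in LV but differed between the OFT libraries, 60.0 and 249 CPM, and HAND1 was 4.28 and 46.0 CPM in the RV libraries against 201 ± 21.0 in LV and 6.18 in Atria. Among LV, RV, OFT and AVC, 1533 of 15063 genes varied at a Benjamini-Hochberg adjusted p below 0.05 (edgeR quasi-likelihood test, 10.2% of the genes). Of the genes fixed beforehand, NR2F1 (adjusted p = 0.001), NR2F2 (0.0017), WNT5A (0.0044), TBX5 (0.0074), TBX2 (0.01), TBX3 (0.017) and IRX4 (0.037) passed in that Benjamini-Hochberg adjusted edgeR test, whereas TNNT2 (0.54), TNNI1 (0.78), NKX2-5 (0.73), ISL1 (0.26) and HAND1 (0.2) did not. The number of varying genes was 3344 with DESeq2, and 1005, 399, 584 and 599 without AVC replicate 1, AVC replicate 2, LV replicate 1 and LV replicate 2.

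**Figure D3:**
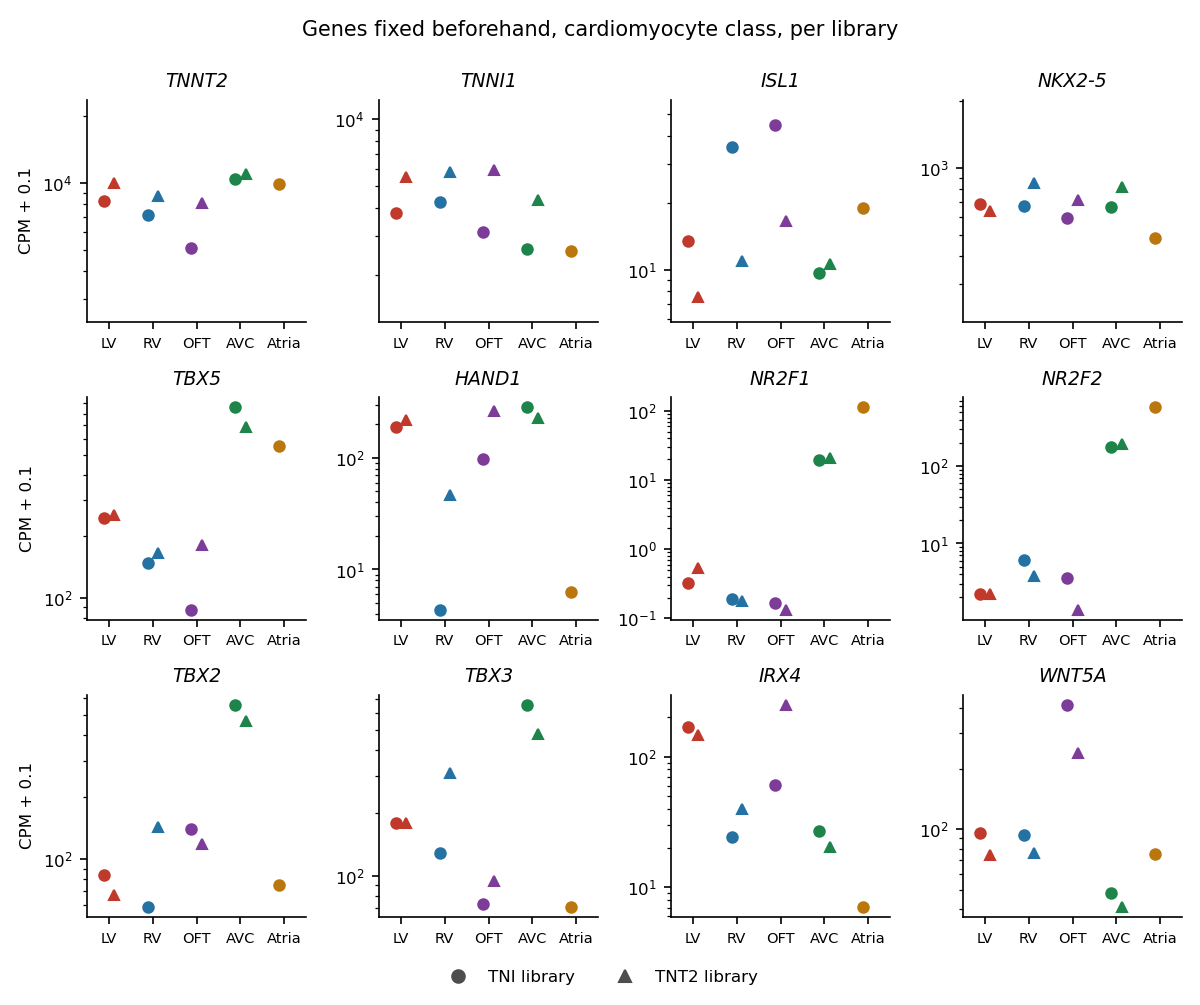
Expression of the 12 genes fixed beforehand in the cardiomyocyte class of each library (CPM + 0.1, log axis), with TNI libraries as circles and TNT2 libraries as triangles. NR2F2 was 579 CPM in Atria and 2.39 CPM in OFT.

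**Figure D4:**
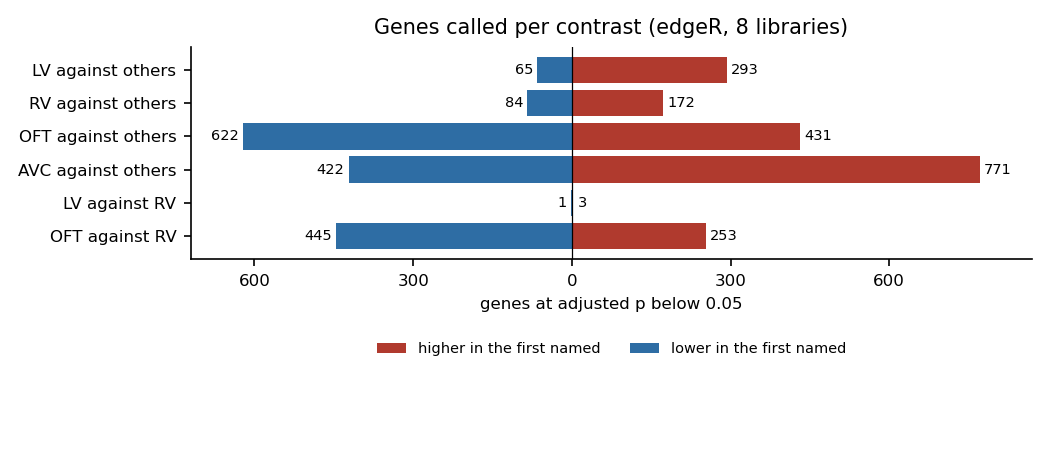
Number of genes at a Benjamini-Hochberg adjusted p below 0.05 in each contrast (edgeR, 8 libraries), higher to the right and lower to the left of 0. AVC against the other subtypes gave 1193 genes and LV against RV gave 4.

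LV cardioids, grown with the lowest activin dose (5 ng/mL) and described in the labels as derived from the first heart field, were set against the mean of RV, OFT and AVC to ask which genes mark them. Natriuretic peptide A, 6 of 19 FGF response genes and 3 of 26 matrix genes were expressed more strongly in LV, and 3 of 16 WNT target genes less strongly. The list tests given for LV passed only with the preset correlation (camera, lowest Benjamini-Hochberg adjusted p = 0.38 with an estimated correlation). NPPA (chromosome 1, 11845709 to 11848345) was 684 ± 146 CPM in LV, 65.5 in RV, 1.45 in OFT and 68.9 in AVC, a log2 fold change of 5.20 ± 0.34 (edgeR, Benjamini-Hochberg adjusted p = 0.0028). In Atria, which was not part of this contrast, NPPA was 1135 CPM, above LV. LHX1, a LIM homeobox transcription factor (chromosome 17, 36936785 to 36944612), was 25.1 ± 6.37 CPM in LV and at most 5.69 CPM in the other replicated subtypes (log2 fold change 4.56 ± 0.32), and was 14.2 CPM in Atria. Of 19 FGF response genes, 6 rose, 1 fell and 12 did not pass, with 9 higher and 3 lower when adjusted over the list alone. Among them were the transcription factor gene ETV4 (log2 fold change 2.98) and the feedback inhibitors SPRY4 (2.69) and IL17RD (2.57). As a group they were higher (camera, Benjamini-Hochberg adjusted p = 0.0003, and adjusted p = 0.47 with an estimated correlation). Of 18 ventricular myocardium genes, 5 rose, 0 fell and 13 did not pass (10 higher and 1 lower adjusted over the list alone), among them the gap junction gene GJA1 (1.45) and IRX3 (1.19). NPPB was also among them (2.28), with 7.81 CPM in LV, 1.10 in RV and 0.0529 in OFT but 68.8 in AVC. This list was higher as well (camera, Benjamini-Hochberg adjusted p = 8.3e-05, and adjusted p = 0.38 with an estimated correlation). The matrix genes TNC (2.46), LAMA4 (1.85) and LAMB1 (1.44) rose among 26 extracellular matrix genes, 23 of which did not pass (6 higher adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.00019, and adjusted p = 0.38 with an estimated correlation). The WNT target genes AXIN2 (-1.94), TNFRSF19 (-1.79) and ZNRF3 (-0.93) fell and DKK2 (2.61) rose among 16 on that list, with 12 not passing and 7 lower and 3 higher adjusted over the list alone. WNT target genes together were lower (camera, Benjamini-Hochberg adjusted p = 0.013, and adjusted p = 0.6 with an estimated correlation). Against the other subtypes, RV too had higher FGF response and ventricular lists (camera, Benjamini-Hochberg adjusted p = 0.012 and 0.0014) and a lower WNT list (4.6e-06). With an estimated correlation these values were 0.64, 0.4 and 0.38. Between LV and RV none of these lists passed (camera, Benjamini-Hochberg adjusted p = 0.11, 0.42 and 0.38), so they do not set LV apart from RV. The cell cycle inhibitor gene CDKN1C (-1.65), DPYSL3 (-2.12) and ADAMTSL2 (-3.32) also fell in LV. In Atria CDKN1C was 22.5 CPM, as in LV, and TNFRSF19 was 24.3 CPM against 26.9 in LV. DPYSL3 was 214 CPM in Atria and 134 in LV, and ADAMTSL2 was 11.4 and 3.37 CPM.

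In all, 358 of 15063 genes differed for LV, 293 higher and 65 lower (edgeR, Benjamini-Hochberg adjusted p below 0.05). All 358 had that direction within each tag, as had the calls of RV, OFT and AVC and of OFT against RV, which is no independent check because the same libraries gave the calls. The count was 2 without LV replicate 1, 26 without LV replicate 2, 59 without AVC replicate 1, 43 without AVC replicate 2 and 611 without RV replicate 1, and it was 1033 with DESeq2 and 126 over all deposited cells. The call of the WNT list was lost over all deposited cells (camera, Benjamini-Hochberg adjusted p = 0.085).

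RV cardioids received 50 ng/mL activin and 500 nM retinoic acid from day 3.5, and the question was which genes separate this anterior second heart field protocol from the other replicated subtypes. In RV 6 of 27 retinoic acid response genes and 2 of 18 anterior second heart field genes rose, and 3 of 16 WNT target genes fell. None of the list calls for RV held with an estimated correlation (camera, lowest Benjamini-Hochberg adjusted p = 0.38 with an estimated correlation). ADAMTS9, a secreted metalloprotease gene (chromosome 3, 64515654 to 64688000), was 1941 ± 14.8 CPM in RV, 799.5 in LV, 175 in OFT and 131 in AVC (log2 fold change 2.88 ± 0.16, edgeR, Benjamini-Hochberg adjusted p = 0.0014). The potassium channel gene KCNQ3 (chromosome 8, 132120858 to 132481019) was 42.5 ± 6.38 CPM in RV and 15.0 CPM in LV (log2 fold change 3.70 ± 0.27). The WNT antagonist gene FRZB (2.74) and the sarcomere gene LMOD2 (2.15) also rose, and the proteoglycan gene SPOCK1 (-5.11) and the WNT agonist gene RSPO3 (-2.65) fell. Of 27 retinoic acid response genes, 6 rose, 1 fell and 20 did not pass, with 14 higher and 4 lower adjusted over the list alone. They included the retinoic acid hydroxylase genes CYP26B1 (2.85) and CYP26A1 (2.73) and HOXB4 (1.45), against NR2F1 (-3.01). CYP26A1 was 19.5 CPM in RV, close to 16.3 in AVC, with 7.01 in LV and 0.222 in OFT. NR2F1 was 0.0849 CPM in RV, 0.0507 in OFT and 0.330 in LV, against 19.8 in AVC. The retinoic acid response genes together were higher (camera, Benjamini-Hochberg adjusted p = 0.00028, and adjusted p = 0.4 with an estimated correlation). The anterior second heart field gene EYA1 (2.73) was 33.3 CPM in RV, at most 9.15 in LV, OFT and AVC, and 30.5 in Atria. IRX1 (2.30) was 59.4 CPM in RV, close to 50.3 in OFT, with 27.8 in LV and 1.22 in AVC. Both rose and 16 of 18 on the anterior second heart field list did not pass (7 higher and 1 lower adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.00087, and adjusted p = 0.64 with an estimated correlation). Without RV replicate 1 that call was lost (camera, Benjamini-Hochberg adjusted p = 0.19). DKK1 (-2.35), CCND1 (-2.28) and LEF1 (-1.30) fell among 16 WNT target genes, 13 of which did not pass (5 lower adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 4.6e-06, and adjusted p = 0.38 with an estimated correlation).

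For RV 256 genes differed, 172 higher and 84 lower (edgeR, Benjamini-Hochberg adjusted p below 0.05). The count was 11 without LV replicate 1, 22 without LV replicate 2, 46 without AVC replicate 1, 29 without AVC replicate 2, 161 without OFT replicate 2, 115 without RV replicate 1 and 519 without RV replicate 2, and it was 1037 with DESeq2 and 164 over all deposited cells. The median of the 33 G2 and M phase genes was -1.34 on the log2 scale (camera, Benjamini-Hochberg adjusted p = 4.7e-08, and adjusted p = 0.64 with an estimated correlation). No member passed with edgeR, 4 had an unadjusted p below 0.05 and 2 passed with DESeq2. The call was lost without RV replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.059), which held 6 proliferating cells.

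OFT cardioids received the same activin and CHIR99021 as RV and no retinoic acid, and the question was which genes mark them against LV, RV and AVC. The natriuretic peptide genes NPPA and NPPB, 10 of 22 atrial, 9 of 18 posterior second heart field and 5 of 32 sarcomere genes fell in OFT. Of 16 WNT target genes 6 rose, and no list call for OFT held with an estimated correlation (camera, lowest Benjamini-Hochberg adjusted p = 0.36 with an estimated correlation). NPPB (chromosome 1, 11857464 to 11858931) was 0.0529 ± 0.0145 CPM in OFT and 68.8 ± 43.1 CPM in AVC (log2 fold change -7.29 ± 0.76, edgeR, Benjamini-Hochberg adjusted p = 0.0025), and NPPA fell by 6.67 on the log2 scale. CDC20B (chromosome 5, 55112995 to 55173175) was 103 ± 125 CPM in OFT and at most 0.695 CPM in LV, RV and AVC (log2 fold change 8.28 ± 0.80). ADAMTS19, a metalloprotease gene, was 1294 ± 18.0 CPM in OFT (log2 fold change 3.72 ± 0.52), and the matrix gene NPNT (4.01), the collagen gene COL21A1 (3.96) and the ephrin receptor gene EPHA3 (3.76) also rose. Of 20 outflow tract genes, 5 rose, 2 fell and 13 did not pass (7 higher and 5 lower adjusted over the list alone). SEMA3C (2.48) was 120 ± 33.5 CPM in OFT, 63.8 ± 50.0 in RV, 43.0 in LV and 3.50 in AVC. It rose with MSX1 (2.32) and WNT5A (2.24), and the list as a whole did not pass (camera, Benjamini-Hochberg adjusted p = 0.13, and adjusted p = 0.66 with an estimated correlation). Without OFT replicate 2 it did (camera, Benjamini-Hochberg adjusted p = 0.016). Of 22 atrial myocardium genes, 10 fell and 12 did not pass (11 lower adjusted over the list alone), among them KCNJ3 (-3.09) and HEY1 (-1.85). The atrial list was lower (camera, Benjamini-Hochberg adjusted p = 2.4e-06, and adjusted p = 0.36 with an estimated correlation). Of 18 posterior second heart field genes, 9 fell and 9 did not pass (2 higher and 11 lower adjusted over the list alone), among them FOXF1 (-3.91), ALDH1A2 (-1.64) and TBX5 (-1.24). TBX5 was 87.5 and 181 CPM in the OFT libraries, against 148 and 167 in RV, 251 ± 5.88 in LV and 772 ± 124 in AVC. It thus did not separate OFT from RV. The posterior second heart field list was also lower (camera, Benjamini-Hochberg adjusted p = 7.8e-06, and adjusted p = 0.36 with an estimated correlation).

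The retinoic acid response also differed in OFT, with 2 of 27 genes higher, 8 lower and 17 not passing (4 higher and 13 lower adjusted over the list alone). CYP26A1 (-5.89) and CYP26B1 (-3.20) fell, whereas the retinol transporter gene STRA6 (2.20) rose, and the list was lower (camera, Benjamini-Hochberg adjusted p = 0.00019, and adjusted p = 0.4 with an estimated correlation). Of 32 sarcomere genes, 5 fell and 27 did not pass (9 lower adjusted over the list alone), among them MYOM2 (-5.22), LMOD2 (-4.42) and TNNI3 (-3.73). Sarcomere genes together were lower (camera, Benjamini-Hochberg adjusted p = 7.4e-06, and adjusted p = 0.64 with an estimated correlation). The WNT target genes TNFRSF19 (2.21), LEF1 (1.35) and AXIN2 (1.26) were among 6 of 16 that rose, DKK2 (-3.52) fell and 9 did not pass (7 higher and 1 lower adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.002, and adjusted p = 0.5 with an estimated correlation), a call lost over all deposited cells (adjusted p = 0.073). S phase genes (median 0.89; camera, Benjamini-Hochberg adjusted p = 0.00018, and adjusted p = 0.66 with an estimated correlation) and G2 and M phase genes (median 1.08; camera, Benjamini-Hochberg adjusted p = 0.0013, and adjusted p = 0.74 with an estimated correlation) were higher in OFT, and both calls were lost without OFT replicate 2 (camera, Benjamini-Hochberg adjusted p = 0.62 and 0.38), the second also without proliferating cells (0.17). Of these lists, 1 of 23 and 0 of 33 members rose with edgeR, 6 and 3 were higher at an unadjusted p below 0.05, and 4 and 0 passed with DESeq2. For OFT 1053 genes differed, 431 higher and 622 lower (edgeR, Benjamini-Hochberg adjusted p below 0.05). The count was 595 without AVC replicate 2, 494 without LV replicate 1, 502 without LV replicate 2, 496 without OFT replicate 1 (256 higher and 240 lower) and 427 without OFT replicate 2 (228 higher and 199 lower), and 1904 with DESeq2. The excess of lower genes was thus not kept without either OFT library.

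AVC cardioids, grown with 10 ng/mL activin, 2 µM CHIR99021, 500 nM retinoic acid and 10 ng/mL BMP4, were set against LV, RV and OFT to ask which genes mark the atrioventricular canal protocol. In AVC 13 of 16 pacemaker and conduction, 7 of 15 atrioventricular canal and 8 of 21 BMP response genes rose, and 7 of 18 ventricular myocardium genes fell. These list calls too were lost with an estimated correlation (camera, lowest Benjamini-Hochberg adjusted p = 0.36 with an estimated correlation). NR2F2 had a log2 fold change of 6.01 ± 0.32 (edgeR, Benjamini-Hochberg adjusted p = 0.00065). GDF10, a ligand of the TGF-beta family (chromosome 10, 47300386 to 47313547), was 236 ± 104 CPM in AVC and at most 9.02 CPM in LV, RV and OFT (log2 fold change 5.98 ± 0.46), and was 11.6 CPM in Atria. HEY2, a ventricular repressor gene (chromosome 6, 125747664 to 125761269), was 2.09 ± 1.32 CPM in AVC and 82.8 ± 2.30 CPM in LV (log2 fold change -5.06 ± 0.62, edgeR, Benjamini-Hochberg adjusted p = 0.0048). Of 16 pacemaker and conduction genes, 13 rose and 3 did not pass (14 higher adjusted over the list alone), among them the sinus node transcription factor gene SHOX2 (5.31), TBX18 (2.44) and the pacemaker channel gene HCN4 (1.56). The pacemaker list was higher (camera, Benjamini-Hochberg adjusted p = 7e-09, and adjusted p = 0.36 with an estimated correlation). Of 15 atrioventricular canal genes, 7 rose and 8 did not pass (13 higher adjusted over the list alone), among them TBX2 (2.38), BMP2 (2.08) and TBX3 (1.94). So was the atrioventricular canal list (camera, Benjamini-Hochberg adjusted p = 1.4e-06, and adjusted p = 0.4 with an estimated correlation). Of 21 BMP response genes, 8 rose and 13 did not pass (12 higher adjusted over the list alone), among them ATOH8 (3.20), SMAD6 (1.40) and ID4 (1.10). BMP response genes together were higher (camera, Benjamini-Hochberg adjusted p = 0.00061, and adjusted p = 0.4 with an estimated correlation). Of 22 atrial myocardium genes, 9 rose in AVC and 0 fell (camera, Benjamini-Hochberg adjusted p = 0.005, and adjusted p = 0.36 with an estimated correlation). The pacemaker list was also high in Atria, with a median log2 difference of 0.41 from the other subtypes (percentile 98.4 of random lists). There 3 of 16 genes lay above all other libraries and 2 below.

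Of 18 ventricular myocardium genes in AVC, 7 fell, 1 rose and 10 did not pass (9 lower and 1 higher adjusted over the list alone). IRX1 (-5.09) and HEY2 (-5.06) fell and NPPB (6.48) rose. Ventricular genes together were lower (camera, Benjamini-Hochberg adjusted p = 0.00017, and adjusted p = 0.38 with an estimated correlation). The anterior second heart field genes FGF8 (-5.16), SIX2 (-3.90) and EYA1 (-2.22) were among 5 of 18 that fell, DLK1 (3.74) rose and 12 did not pass (6 lower and 1 higher adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.0013, and adjusted p = 0.64 with an estimated correlation). Among 18 posterior second heart field genes, 9 rose, 2 fell and 7 did not pass (11 higher and 4 lower adjusted over the list alone). NR2F1 (7.47) and OSR1 (3.52) rose and HOXB2 (-1.94) fell, and the list was higher (camera, Benjamini-Hochberg adjusted p = 0.0035, and adjusted p = 0.45 with an estimated correlation). For AVC 1193 genes differed, 771 higher and 422 lower (edgeR, Benjamini-Hochberg adjusted p below 0.05). The split was 831 higher and 789 lower without AVC replicate 1 and 1287 higher and 1073 lower with DESeq2. The count was 114 without AVC replicate 2, 532 without LV replicate 1 and 473 without LV replicate 2, and it was 2360 with DESeq2 and 696 with Atria among the other subtypes.

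**Figure D5:**
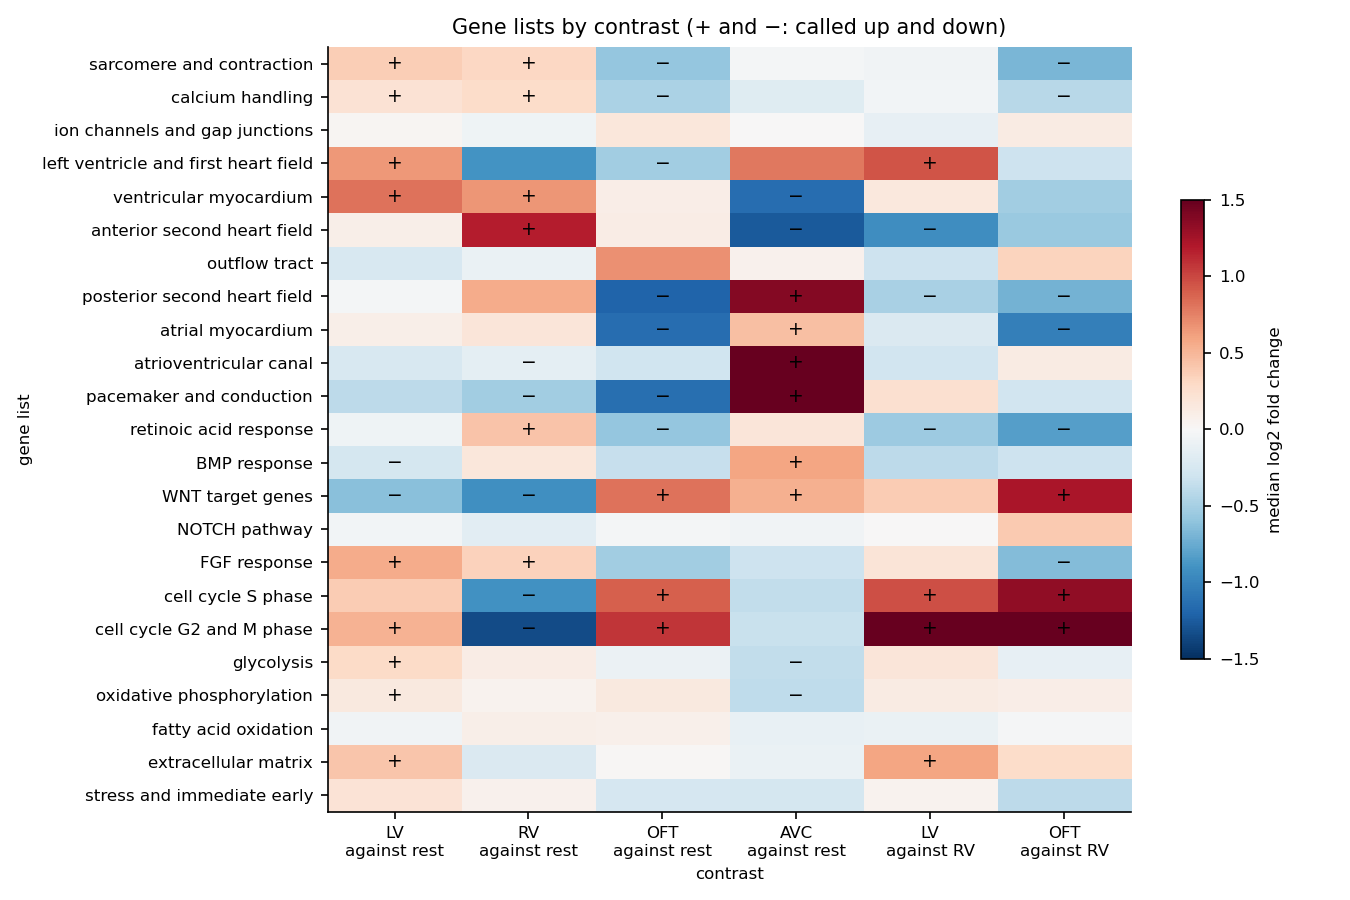
Median log2 fold change of each of the 23 gene lists in the 6 contrasts; + and − mark lists higher and lower at a Benjamini-Hochberg adjusted p below 0.05 (camera, preset correlation of 0.01). The marks stand for 58 of 138 tests, and 0 of them passed with an estimated correlation.

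LV and RV were compared directly to ask what separates the ventricular protocols. These differ in activin, CHIR99021, retinoic acid and BMP4 and in the day of collection. Only 4 genes passed the threshold, and the list medians that differed passed with the preset correlation alone (camera, lowest Benjamini-Hochberg adjusted p = 0.36 with an estimated correlation). S100A10 (chromosome 1, 151982915 to 151994390) was 32.4 ± 0.998 CPM in LV and 3.79 ± 0.702 in RV (log2 fold change 3.09 ± 0.29, edgeR, Benjamini-Hochberg adjusted p = 0.038). The axon guidance ligand gene SLIT2 (log2 fold change 1.39 ± 0.13) and the glycosyltransferase gene C1GALT1 (1.32 ± 0.12) were also higher in LV. TENM2, a teneurin gene, was lower in LV (log2 fold change -3.43 ± 0.31) and lay outside the rule for naming genes, so it was chosen after its values were seen. The median of the 9 left ventricle and first heart field genes was 0.95 on the log2 scale (camera, Benjamini-Hochberg adjusted p = 0.00039, and adjusted p = 0.4 with an estimated correlation), and 4 were higher adjusted over the list alone. NPPA was 684 against 65.5 CPM (log2 fold change 3.38 ± 0.48, edgeR, Benjamini-Hochberg adjusted p = 0.089) and HAND1 201 against 25.1 CPM (3.00 ± 0.95, adjusted p = 0.32). Retinoic acid response genes had a median of -0.54 (camera, Benjamini-Hochberg adjusted p = 0.00038, and adjusted p = 0.4 with an estimated correlation), with 7 lower and 1 higher adjusted over the list alone. Extracellular matrix genes had a median of 0.60 (camera, Benjamini-Hochberg adjusted p = 8.7e-06, and adjusted p = 0.36 with an estimated correlation). G2 and M phase genes had a median of 1.50 (camera, Benjamini-Hochberg adjusted p = 2.3e-08, and adjusted p = 0.64 with an estimated correlation), and S phase genes had a median of 0.96 (camera, Benjamini-Hochberg adjusted p = 2.5e-05, and adjusted p = 0.66 with an estimated correlation). No member of the cell cycle lists passed with edgeR or DESeq2, 2 and 2 were higher at an unadjusted p below 0.05, and RV replicate 1 held 6 proliferating cells. The S phase call was lost without proliferating cells (camera, Benjamini-Hochberg adjusted p = 0.22) and without RV replicate 1 (0.068), while the G2 and M phase call had 0.011 and 0.014. Anterior second heart field genes (median -0.93; camera, Benjamini-Hochberg adjusted p = 0.023, and adjusted p = 0.66 with an estimated correlation) and posterior second heart field genes (median -0.49; camera, Benjamini-Hochberg adjusted p = 0.037, and adjusted p = 0.6 with an estimated correlation) were lower in LV, and both calls were lost without RV replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.84 and 0.26) and over all deposited cells (0.088 and 0.23). The first was also lost without LV replicate 2 (0.096 by camera), and the second without LV replicate 1 (0.088) and AVC replicate 2 (0.051). No member of either passed with edgeR, 5 and 7 were lower and 1 and 2 higher at an unadjusted p below 0.05, and 4 and 1 were lower and 1 and 1 higher with DESeq2.

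No member of the first heart field, retinoic acid response and extracellular matrix lists passed between LV and RV over all genes with edgeR, and 3 of the first of these lists passed with DESeq2, 6 lower and 1 higher of the second, and 4 higher and 1 lower of the third. At an unadjusted p below 0.05 the numbers were 5 higher and 1 lower, 12 lower and 1 higher, and 10 higher and 1 lower. In all, 4 of 15063 genes differed between LV and RV (edgeR, Benjamini-Hochberg adjusted p below 0.05), 1605 had an unadjusted p below 0.05, and DESeq2 gave 541. With edgeR the count was 0 over all deposited cells and without LV replicate 1, LV replicate 2, AVC replicate 1 or AVC replicate 2, and 24, 33, 17 and 45 without OFT replicate 1, OFT replicate 2, RV replicate 1 (7 higher and 10 lower) and RV replicate 2.

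OFT and RV shared their activin and CHIR99021 doses and were compared to ask what separates them. They differed in the WNT inhibitor and in the retinoic acid given to RV from day 3.5. Effects of these steps cannot be told apart here. In OFT 7 of 27 retinoic acid response, 4 of 32 sarcomere and 6 of 18 posterior second heart field genes were lower than in RV, and 5 of 16 WNT target genes were higher. With an estimated correlation no list passed (camera, lowest Benjamini-Hochberg adjusted p = 0.36 with an estimated correlation). LMOD2, which encodes leiomodin of the thin filament (chromosome 7, 123655807 to 123664290), was 4.85 ± 0.691 CPM in OFT and 146 ± 9.60 CPM in RV (log2 fold change -4.93 ± 0.19, edgeR, Benjamini-Hochberg adjusted p = 0.00018). LRRTM3 (-7.31), KCNQ3 (-5.85) and NPPA (-5.52) also fell, and CDC20B (7.20), the WNT agonist gene RSPO2 (6.11) and ADAMTS19 (4.58) rose. Of 27 retinoic acid response genes, 7 fell, 1 rose and 19 did not pass (12 lower and 1 higher adjusted over the list alone). CYP26A1 (-6.47) and CYP26B1 (-4.54) fell and STRA6 (2.50) rose, and the list was lower (camera, Benjamini-Hochberg adjusted p = 2.5e-06, and adjusted p = 0.36 with an estimated correlation). Of 32 sarcomere genes, 4 fell, among them MYOM2 (-4.90) and TNNI3 (-3.32), and 28 did not pass (8 lower adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 2.4e-06, and adjusted p = 0.64 with an estimated correlation). Of 18 posterior second heart field genes, 6 fell, among them FOXF1 (-3.35) and ALDH1A2 (-2.04), and 12 did not pass (9 lower adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 8.4e-06, and adjusted p = 0.36 with an estimated correlation). DKK1 (2.82), CCND1 (2.32) and LEF1 (1.99) were among 5 of 16 WNT target genes that rose, with 11 not passing (9 higher and 1 lower adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 1.2e-05, and adjusted p = 0.4 with an estimated correlation). The BMP response genes split, with 3 higher, among them BMP4 (2.81), 7 lower, among them BMP10 (-5.93) and SMAD6 (-1.11), and 11 of 21 not passing (4 higher and 9 lower adjusted over the list alone). As a group they did not pass (camera, Benjamini-Hochberg adjusted p = 0.16, and adjusted p = 0.66 with an estimated correlation). The medians of the G2 and M phase genes, 1.81 (camera, Benjamini-Hochberg adjusted p = 5.5e-07, and adjusted p = 0.66 with an estimated correlation), and of the S phase genes, 1.32 (camera, Benjamini-Hochberg adjusted p = 6.3e-07, and adjusted p = 0.64 with an estimated correlation), were higher in OFT. No member of either list passed with edgeR, 8 and 14 were higher at an unadjusted p below 0.05, and 3 and 5 passed with DESeq2. Proliferating cells made up 21.2% of OFT replicate 2 and 0.0735% of RV replicate 1, and without them the p rose for the G2 and M phase list and the S phase list (camera, Benjamini-Hochberg adjusted p = 0.022 and 0.00012).

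In all, 698 genes differed between OFT and RV, 253 higher and 445 lower in OFT (edgeR, Benjamini-Hochberg adjusted p below 0.05). The count was 398, 401, 330, 330, 458 and 226 without AVC replicate 1, AVC replicate 2, LV replicate 1, LV replicate 2, OFT replicate 1 and OFT replicate 2, and 1566 with DESeq2. The excess of lower genes was lost without OFT replicate 1 (230 higher and 228 lower) and without OFT replicate 2 (112 higher and 114 lower).

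Atria cardioids, which received 500 nM retinoic acid in both patterning steps, were set against the other subtypes to ask which genes lie outside the range of all 8 other libraries. With 1 library no gene was tested, and a gene counted when it differed at least 2-fold from the mean of the other subtypes and lay outside that range. Atrial myocardium and retinoic acid response genes were high in Atria, and BMP response genes were low. NR2F1 (chromosome 5, 93583224 to 93594615) was 113 CPM in Atria and 19.8 ± 0.924 CPM in AVC, a log2 difference of 7.95 from the mean of the other subtypes, and CYP26A1 (chromosome 10, 93073475 to 93077890) had a difference of 7.36. Of 22 atrial myocardium genes, 10 lay above and 1 below all other libraries, among them the potassium channel genes KCNJ3 (5.19) and KCNA5 (4.35) and NPPA (4.69), against sarcolipin, SLN (-3.40). Their median difference was 1.89, at percentile 100 of 10000 random gene lists of the same size and similar mean expression. The ion channel and gap junction list lay at percentile 62.9, with 5 of 20 above and 1 below. Retinoic acid response genes had a median of 0.99 (percentile 100), with 14 of 28 above and 2 below. BMP response genes had a median of -1.23 (percentile 0), with 9 of 22 below, among them ID1 (-3.80) and SMAD6 (-2.67), and 3 above, among them BMP10 (4.77), and the Atria protocol contained LDN-193189, an inhibitor of BMP receptors. The NOTCH pathway list had a median of -0.27 (percentile 2.85), with 3 of 17 above and 3 below, HES1 at -2.05 and HEY1 at 2.89. Ventricular myocardium genes had a median of -0.53 (percentile 0.0900), with 3 of 18 above and 4 below, MYL2 at -3.94 and IRX4 at -3.13.

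By this rule 1523 of 15383 genes stood out in Atria, 916 higher and 607 lower. The number was 2748 at 1.5-fold and 765 at 3-fold, and over all deposited cells 1388 higher and 529 lower. Atria was also set against AVC, since the labels describe both protocols as deriving from the posterior second heart field, and 1902 of 14926 genes differed at least 2-fold and lay outside both AVC values, 951 higher and 951 lower. The potassium channel genes KCNA4 (log2 difference 6.50) and KCNA5 (5.10), CYP26A1 (5.61) and the angiopoietin gene ANGPT1 (5.02) were higher in Atria, and HAND1 (-5.36), MSX2 (-4.82), RSPO3 (-5.85) and endoglin, ENG (-6.23), were lower. Against AVC the number was 3543 at 1.5-fold and 954 at 3-fold. The even split was not stable, with 1437 higher and 939 lower over all deposited cells, 834 higher and 1031 lower without AVC replicate 1 and 1249 higher and 972 lower without AVC replicate 2.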

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

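Both tests of an explanation given here were chosen only after the result was seen. The subtype differences in the share of proliferating, EC and Endoderm cells were computed within the TNI libraries and within the TNT2 libraries, 18 comparisons in all. In 6 of them the sign was opposite in the tags, and in 4 the exact intervals of the shares were also apart in both tags. With 1 library per subtype and tag these differences between the tags were not tested, and spread between libraries alone can turn a sign. The proliferating share of LV minus OFT was 3.30 percentage points in TNI and -13.7 in TNT2, a gap of 17.0. For OFT minus AVC it was -1.07 in TNI and 17.8 in TNT2, TNI minus TNT2 being -18.9. The EC share of LV minus AVC was -0.900 in TNI and 1.21 in TNT2, TNI minus TNT2 being -2.11. The Endoderm share of LV minus AVC was 5.35 in TNI and -1.32 in TNT2, a gap of 6.67.

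Both differences in the proliferating share rest on OFT, where replicate 2 had 6.07 times the share of replicate 1. A different boundary of the authors' class is argued against by the G2 and M phase genes over all cardiomyocyte-class cells, whose median was -2.29 on the log2 scale in replicate 1 relative to replicate 2. Droplets of more than 1 cell stay open, since leaving out the top 2% of cells by UMI count, which gave a ratio of 6.33, could not have lowered it below 5.49. The tag, the leading number of the titles and the culture differed together between these libraries and cannot be told apart, and no biological explanation was tested.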

How the results depend on the processing

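The alternatives without proliferating cells, without the top 2% of cells by UMI count before summing and with thinned library sums were chosen only after the data were seen. Of 186 alternative values of the 16 counts and shares, 127 stayed within 1.5 times the count or within 1 SD of the share (for Atria, within its exact interval) and 59 did not. For a share, leaving out 1 of 2 libraries always gives a value within 1 SD of the mean. Those runs are among the 127 and could not have moved. With DESeq2 the counts were 3344 among the 4 subtypes, 1033 for LV, 1037 for RV, 1904 for OFT, 2360 for AVC, 541 for LV against RV and 1566 for OFT against RV. Over all deposited cells they were 126 for LV, 164 for RV and 0 for LV against RV with edgeR, where the unadjusted count was 1605 in the class, and the cause was not tested. AVC gave 696 with Atria among the others. The size rule gave 2748 and 765 genes for Atria and 3543 and 954 against AVC at 1.5-fold and 3-fold, by construction. Leaving out 1 library gave 399 to 2179 genes among the 4 subtypes, 2 to 611 for LV, 11 to 519 for RV, 427 to 1366 for OFT, 114 to 1692 for AVC, 0 to 45 for LV against RV, 226 to 935 for OFT against RV, 1493 to 1905 for Atria, 1865 to 2221 for Atria against AVC and 53 to 67 list calls. Of the 58 list calls 0 passed with an estimated correlation in camera. The cardiomyocyte share of AVC was 95.8% among cells with at least 4392 UMI counts, which left out 3193 cells of AVC replicate 2, and 97.0% without the top 2% by UMI count, and that of Atria was 89.3%. Without 1 library the share ranged over 91.8 to 96.8% in LV, 98.7 to 99.6% in RV, 99.0 to 99.98% in OFT and 96.3 to 96.7% in AVC. With the tag as a block the counts were 570 for LV and 12 for LV against RV, no other count moved by over 1.5 times, and of the list calls that of the posterior second heart field between LV and RV was lost (camera, Benjamini-Hochberg adjusted p = 0.083) and that of oxidative phosphorylation in OFT was gained (0.036). The shift between tags correlated across genes at 0.347 to 0.494 among LV, RV and OFT, whose titles share their leading numbers, and at 0.0322 to 0.190 with AVC, and since the labels state no pairing the fit without the block was kept. Of 1751 runs on 103 named gene results, 1537 kept direction and threshold, 214 lost the threshold and 0 reversed. These genes were chosen without overlap between the libraries of the sides. Leaving out a library could therefore hardly reverse them, and the 0 is no independent check. A lower and a higher clustering resolution were not run, since no clusters were made here.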

Other observations

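All fits of EC cells and all tests of an explanation given here were chosen only after the result was seen. Single genes differed between the EC cells of LV and AVC, and those named here were chosen after their values were seen, without a test of a list. SOX9, a transcription factor of heart valve mesenchyme, was 9.11 ± 4.36 CPM in LV and 200.2 ± 8.38 in AVC (log2 fold change -4.45), and TWIST1 was 18.3 ± 1.63 CPM in LV and 172 ± 40.2 in AVC (log2 fold change -3.19). NPR3, a natriuretic peptide receptor gene of the endocardium, was 432 ± 38.2 CPM in LV and 91.7 ± 8.42 in AVC (log2 fold change 2.27), and GATA2 was 164 ± 9.08 CPM in LV and 32.1 ± 0.597 in AVC (log2 fold change 2.39). NPR3 was 812 and 818 CPM in the RV libraries and 123 CPM in Atria. In all, 44 of 11863 genes passed between LV and AVC EC cells (edgeR, Benjamini-Hochberg adjusted p below 0.05), with 991 at an unadjusted p below 0.05. Leaving out 1 library left 0 calls without AVC replicate 1, 0 without AVC replicate 2, 1 without LV replicate 1 and 3 without LV replicate 2. NR2F2, which separated AVC and Atria cardiomyocytes from the rest, lay between 117 and 721 CPM in the EC cells of all 8 libraries with enough of them. Transcripts of 4 abundant cardiomyocyte genes were present in EC cells at 6.73% to 26.1% of their cardiomyocyte-class level, with a median of 14.3%, so values in EC cells include RNA of cardiomyocytes.

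In the Endoderm cells AFP was 3085 CPM in LV replicate 1, 5325 and 8414 CPM in AVC and 1529 CPM in Atria, against 1.13 CPM in OFT replicate 1 and 1.93 CPM in RV replicate 1. In that order these libraries held 778, 158, 80, 295, 54 and 25 Endoderm cells. SOX2, a gene of anterior endoderm, was 72.6 CPM in Atria, 28.9 in RV replicate 1 and 3.43 in AVC replicate 2. It was 0.611 CPM in AVC replicate 1, 0.788 in LV replicate 1 and 0.566 in OFT replicate 1. CDX2, a gene of posterior endoderm, was 42.0 and 42.9 CPM in AVC and 36.5 CPM in Atria. It was 5.10 CPM in OFT replicate 1, 0.315 in LV replicate 1 and 0 in RV replicate 1.

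Between LV and RV 4 genes were called, and RV replicate 2 correlated best with an LV library. The wide spread between the RV libraries stays open, since the same libraries gave 698 genes between OFT and RV, but the LV and RV count was 17 without RV replicate 1 and 45 without RV replicate 2. LV cells mixed into RV replicate 2 are argued against by 11 genes of at least 20 CPM in both LV libraries whose counts there allow at most 20% of LV cells, with 4.01% from CXCL14 and 10.8% from NPPA. The covariance across genes of the LV minus RV difference in TNI with that in TNT2 was 0.267 (bootstrap 95% interval over genes 0.249 to 0.284). It was 0.573 (0.538 to 0.611) for RV and OFT, which goes with smaller differences between the ventricular subtypes in these libraries. The intervals cover only the draw of genes, which are not independent replicates, and leave out the spread between libraries. The day of collection differed between LV and RV and stays open.

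In LV, RV and OFT the TNI libraries had lower sarcomere genes, with medians of -0.44, -0.42 and -0.63 on the log2 scale relative to TNT2, and higher anterior second heart field genes, with 0.45, 1.03 and 0.95. Library depth is argued against by the ratios of median UMI counts per cell, TNI to TNT2, which were 1.71 in LV but 0.855 in RV, while the list medians had the same signs in both. More proliferating cells in TNT2 libraries are argued against by the 6 of 6 medians that kept their sign and at least 50% of their size without those cells. In AVC the sarcomere median was -0.28, in the same direction and at least 50% of the smallest of the others, which is consistent with a difference common to the tags for these genes. For the anterior second heart field genes, whose AVC median was -0.31, such a difference stays open, since 10 of 18 lay below 10 CPM in AVC and there was 1 library per tag. The titles of these TNI libraries share 1 leading number and those of TNT2 another, so the tag and a batch marked by that number cannot be told apart there, and a less advanced state of the TNI cultures stays untested.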
